A study of Solanum lycopersicum with 12 samples.

How the data were processed

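The samples were fruits of 2 tomatoes (Solanum lycopersicum), a yellow one with the number 19 and a red one with the number 20, taken 40 days after anthesis (color break) and 55 days after anthesis (maturity). Each combination of tomato and stage held 3 libraries, which gave 4 groups and 12 libraries, and every library was assigned to its group from the labels. Per the labels' protocols, RNA was extracted with Trizol, mRNA was captured on oligo(dT), and strand-marked (dUTP) libraries were read from both ends on an Illumina instrument. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. They also do not say whether seeds were removed from the fruits.

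Per the submitters' processing notes, the tools used were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, with no role or order. How each was set, the genome build, the annotation and whether the counting used strand are not given in the sources used here. The authors deposited 1 table for the series with a read count and an FPKM value (fragments per kilobase of gene and 1e6 mapped fragments) per gene and library. The count columns deposited by the authors hold whole numbers, so they were taken as raw counts. Their totals were 58647743, 50987410 and 60854667 in yellow and 59678360, 59512008 and 52027250 in red at color break, and 60484460, 58859669 and 50963462 in yellow and 52954311, 57307569 and 58158213 in red at maturity. In the FPKM columns deposited by the authors, the depth implied by the ratio of counts to FPKM matched the table's own totals, relative to the first yellow color break library, within a factor of 1.0 to 1.0175 except for replicates 2 and 3 of red at maturity (1.0652 and 1.0565). All columns of values matched 1 library. Coordinates, chromosomes and descriptions were taken from the table as given, and 4835 of its 24215 genes carry a description.

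The design fixed before the data were examined assumed FPKM values and a limma-trend test on log2(FPKM + 1), with a change to edgeR if counts were present. Since they were, the test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16, R 4.3.3) on the counts with TMM scaling, and the limma fit became an alternative. Genes with an FPKM of at least 1 in at least 3 libraries were tested, 15974 in all. All 12 libraries entered 1 fit with a mean per group and no further term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, and every adjusted p of a single gene comes from this test. The comparisons were red against yellow at each stage, maturity against color break in each tomato, and the difference of the stage changes (red minus yellow). Fold changes are given on the log2 scale with their standard error (SE), and FPKM as mean ± SD of 3 libraries.

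The lists of genes were fixed before the data were examined: lycopene synthesis, later carotenoid steps, flavonoids, chlorophyll breakdown and plastid regulators, ripening regulators, ethylene, cell wall softening, aroma volatiles, sugar and starch, organic acids and amino acids, steroidal glycoalkaloids, vitamins E and C, the cuticle, nuclear photosynthesis genes, seed, vascular bundles, heat shock, defence, ribosomal proteins and the cell cycle. Members were matched by Solyc identifier or by words of the description. One member (CYP97C11) was left out because its annotation in the table named another function. Lists were tested with limma's camera (limma 3.58.1) with a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison, then again with an estimated correlation and with fry. With an estimated correlation 7 of the 85 list tests passed, against 36 with the preset one, and the adjusted p with an estimated correlation is printed beside each list test that passed with the preset one. In each of those 36 tests the list's median, mean and test had the same sign. Glycoalkaloids and the cuticle had under 5 tested members and were not tested as lists. None of the 6 vascular genes of the table passed the filter, so that list has no result. In each list without a call, DESeq2 1.42.0 and limma on log2(FPKM + 1) also called 0 members. For these lists the number of members at an unadjusted p under 0.05 is given. Most of those members that also passed the adjusted p went uncalled only because they changed by less than the minimum.

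Named genes followed a rule fixed before the data were examined. It takes, in each comparison of 2 groups, the 5 called genes with the largest rise and the 5 with the largest fall, among genes whose groups do not overlap, with a mean FPKM of at least 5 in the higher group and a symbol or description. It adds up to 4 called members of each list by size of change, and 17 genes that are always named. For the difference of stage changes it takes the 5 largest in each direction. Chance separates 2 groups of 3 in 10% of genes. Of the genes always named, LCYE and GLK2 were below the filter, and SGR1, LIN5 and ALMT9 were not analysed here. Where several genes of a family are nearly identical (chalcone synthases, phenylalanine ammonia-lyases, chlorophyll a/b-binding proteins, Rubisco small subunits, histones, oleosins), reads could be shared between them, and values of single members are uncertain. The same holds for overlapping and antisense genes, since the use of strand in counting is not stated.

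The procedure was tested on simulated counts with 200 genes changed by known folds. The changed genes had at least 50 expected counts per library, with as many rises as falls, and all other genes had equal means in all groups. The recoveries therefore do not cover genes with fewer counts or data where falls outnumber rises. Of 50 genes changed 3-fold, 100% were called in the comparison of the tomatoes at color break, 92% at maturity, 98% in the yellow stage comparison, 98% in the red one and 94% in the difference of stage changes. None of 50 genes changed 1.5-fold was called in any of these, since that lies under the minimum fold change, and 1, 0, 1, 1 and 6 of the unchanged genes were called. At these depths the median SE of a log2 fold change was 0.085, and 0.121 for the difference of stage changes. A fold against a group with no counts was computed against a floor of 3 counts over the group and is written as a lower bound that covers counting error only.

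Alternatives fixed before the data were examined were the scaling, the filter on low values, the pseudocount, the limma fits, DESeq2, a replicate block and the omission of each library in turn. Library totals without TMM and the depth implied by the authors' FPKM were added after seeing the data. Some scalings moved the median of all genes by over 0.1 on the log2 scale: rescaling FPKM to a fixed total moved it by up to 0.168 for the tomatoes at maturity, 0.228 for the red stage comparison and 0.196 for the difference of stage changes. Enrichment of GO terms given in the table was also added after seeing the data, as Fisher's exact test of called genes against the tested genes with a term, over 709 terms of 10 to 500 genes and 5672 tests adjusted together. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.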

Results

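Messenger RNA was sequenced from fruits of a yellow and a red tomato that are closely related, in a series on the expression of flavor and color. Fruits were sampled at color break, 40 days after anthesis, when the green fruit begins to turn, and at maturity, 55 days after anthesis. Each of the 4 groups held 3 libraries. Total counts per library ran from 50963462 in yellow at maturity to 60854667 in yellow at color break. Of 24215 genes in the table, 15974 passed the filter and were tested. The coefficient of variation between replicates, from edgeR's common dispersion, was 0.0869. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 5.29 to 31.18), so each library was counted once.

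The first principal component of log2 CPM (counts per 1e6) took 65.0% of the variance over the 15974 genes and the second 19.5%. On the first, both tomatoes lay at low values at color break (-43.0 to -30.58), yellow at maturity lay at 8.16 to 9.02, and red at maturity lay farthest along. In red at maturity, replicate 1 lay at 55.77 and replicates 2 and 3 at 69.67 and 70.6, and the chi-square per degree of freedom was 31.18 and 29.41 for the pairs with replicate 1 and 11.51 for the other pair.

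**Figure D1:**
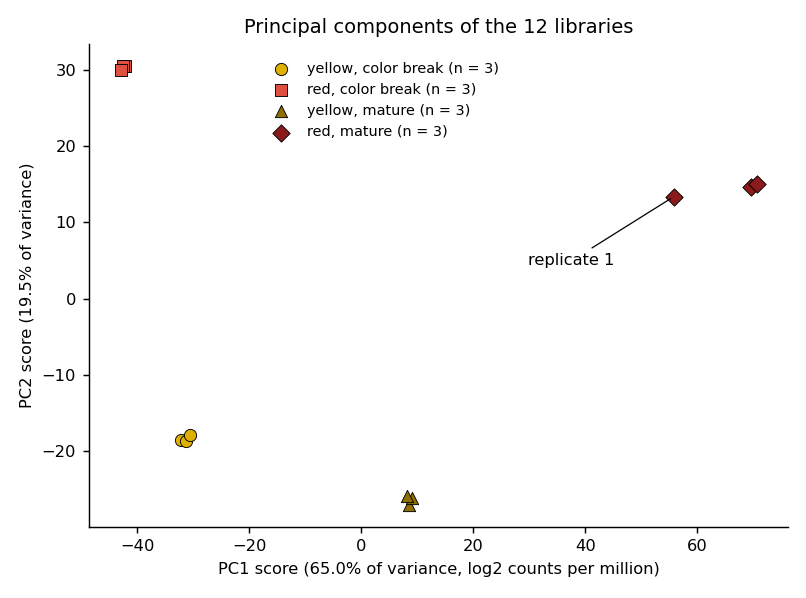
The 12 libraries on the first and second principal components of log2 CPM (axes in component units with the percent of variance), each point a library and each color and shape a group. Replicate 1 of red at maturity lies at 55.77 on the first component, apart from 69.67 and 70.6 in the other replicates.

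The question at color break was in which genes the red and the yellow tomato differ when ripening starts. Of the 14 flavonoid genes tested, 10 were higher in the red tomato, several of them by far. Transcript of CHS1 (Solyc09g091510, chromosome 9, 71250708 to 71252868), a chalcone synthase, which makes the first flavonoid intermediate, was 137-fold higher: 73.5 ± 2.2 FPKM (mean ± SD, n = 3) in red against 0.525 ± 0.0733 in yellow (log2 fold change 7.10 ± 0.13 SE, edgeR adjusted p = 1.49e-13). CHS2, the second chalcone synthase gene, was 123-fold higher (6.94 ± 0.14, adjusted p = 2.4e-13), and F3H, the flavanone 3-hydroxylase, 48.7-fold higher (5.60 ± 0.11, adjusted p = 1.49e-13). MYB12 (Solyc01g079620, chromosome 1, 78605034 to 78608476), the MYB factor that switches on flavonoid genes in the tomato peel, was 22.1-fold higher, at 10.2 ± 0.291 FPKM in red and 0.456 ± 0.0924 in yellow (4.47 ± 0.19, adjusted p = 4.67e-10). Of the 14 flavonoid genes tested, 10 rose, 0 fell and 4 were not called, with the same counts adjusted over the list alone (median log2 fold change 3.36, list test adjusted p = 4.06e-100, adjusted p = 8.38e-06 with an estimated correlation).

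Outside that list, Solyc09g090900, described as the large subunit of a chloroplast 3-isopropylmalate dehydratase, which acts in leucine synthesis, was 69.8-fold higher in red (6.13 ± 0.29, adjusted p = 1.89e-09). The largest falls under the naming rule (described genes of at least 5 FPKM) were in the metallothionein-like gene Solyc06g076140, 25.6-fold lower in red (498 ± 36.9 FPKM in yellow, 19.5 ± 3.35 in red, adjusted p = 1.9e-08), and in LOXC. LOXC, the lipoxygenase that starts the synthesis of green-leaf aroma volatiles, stood at 842 ± 3.66 FPKM in yellow and 193 ± 3.07 in red (-2.12 ± 0.03, adjusted p = 8.9e-15). Solyc01g102290 followed at 4.02-fold lower in red and the histone H2A gene Solyc01g099410 at 3.68-fold lower. Another lipoxygenase gene, Solyc01g099180, was lower as well (-1.84 ± 0.45, adjusted p = 0.00513), and without replicate 3 of yellow at color break it was at -0.68 and not called.

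Color itself in tomato comes mainly from carotenoids. Of 14 genes of lycopene synthesis 0 rose and 1 fell: GGPPS2, which makes the geranylgeranyl diphosphate precursor, was 2.15-fold lower in red (-1.11 ± 0.06, adjusted p = 4.34e-09). PSY1, the phytoene synthase of the ripening fruit, was at 2640 ± 74.4 FPKM in red and 1400 ± 24.7 in yellow (0.91 ± 0.02, adjusted p = 1.44e-12), under the minimum fold change. CRTISO, the prolycopene isomerase (-0.03 ± 0.04, adjusted p = 0.575), and CYCB, the fruit lycopene beta-cyclase (0.17 ± 0.06, adjusted p = 0.0271), were not called. Of the 10 later carotenoid genes 1 rose, NCED1, which cleaves carotenoids toward abscisic acid (1.72 ± 0.06, adjusted p = 2.8e-11). None of 13 ripening regulators was called by edgeR, with 7 at an unadjusted p under 0.05. At an adjusted p under 0.05 there were 6, all under the minimum change (largest absolute log2 fold change 0.99). RIN, a MADS-box factor needed for ripening, stood at 235 ± 5.39 FPKM in red and 237 ± 4.34 in yellow. NOR (-0.09 ± 0.04), the softening genes PG2A (-0.01 ± 0.04) and PL (-0.10 ± 0.04) and the ethylene genes ACS2 (-0.54 ± 0.04) and ACO1 (0.25 ± 0.03) were not called either.

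Of 15 nuclear photosynthesis genes 8 rose in red and 0 fell (list test adjusted p = 0.00314, adjusted p = 0.235 with an estimated correlation), among them the chlorophyll-binding gene Solyc03g005760 (2.45 ± 0.23, adjusted p = 1.42e-06) and RBCS-2A, a Rubisco small subunit (1.58 ± 0.15, adjusted p = 1.34e-06). Of 50 cell cycle genes 13 fell and 0 rose (adjusted p = 6.13e-06, adjusted p = 0.235 with an estimated correlation), with the histone H3 gene Solyc01g086820 at 26.5 ± 1.53 FPKM in red and 70.2 ± 5.83 in yellow. Among 12 defence genes 4 rose and 0 fell, including the chitinases CHI3 (2.08 ± 0.11) and CHI9 (1.88 ± 0.17). In the ethylene list 2 of 23 rose, ACO5 (2.61 ± 0.08) and ACO6 (2.13 ± 0.10), both ACC oxidases, the last enzyme of ethylene synthesis. Cell wall softening had 2 falls among 9 genes, the mannanase gene MAN4 (-1.34 ± 0.13) and CEL1, which was not called without replicate 1 of yellow (-0.98) or replicate 3 of red (-0.99) at color break. Sucrose synthase SUS1 (1.33 ± 0.05) was the only call among 20 sugar genes, and aroma volatiles had 1 rise, PAR2, and 1 fall, LOXC, among 9 genes. None of these list tests passed (adjusted p = 0.0625 for ethylene, cell wall, sugar and defence, and 0.0561 for aroma volatiles). Vitamins E and C (0 rose, 1 fell of 11), heat shock (0 and 1 of 12) and ribosomal proteins (0 and 1 of 70) had 1 call each. There was no edgeR call among 5 chlorophyll genes (4 at an unadjusted p under 0.05), 10 acid and amino acid genes (8), 4 glycoalkaloid genes (3), 4 cuticle genes (2) and 5 seed markers (4; median log2 fold change 0.79). Each list's counts were the same when adjusted over the list alone.

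In all, edgeR called 991 of the 15974 genes at color break, 658 higher and 333 lower in red. Reads of the similar CHS1 and CHS2, and of histone and chlorophyll-binding genes, could be shared within each family.

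**Figure D2:**
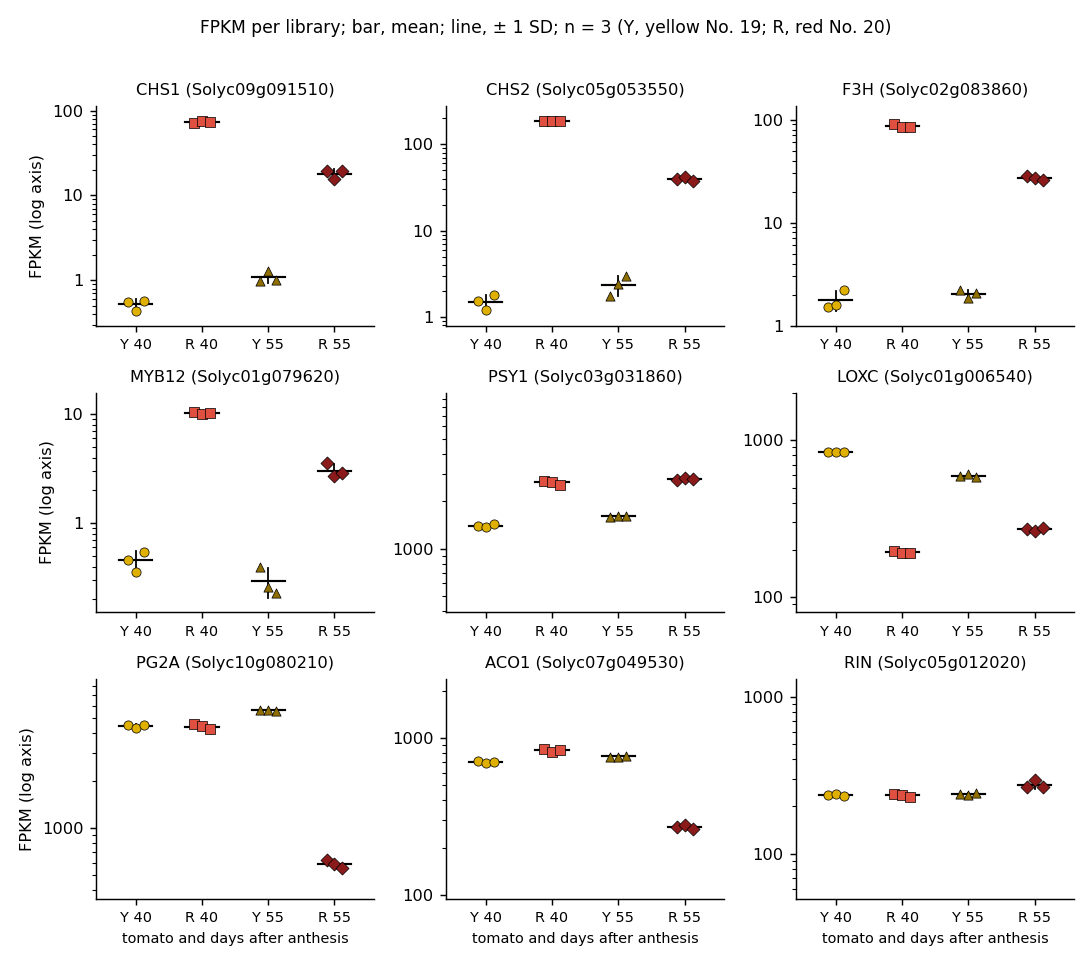
FPKM (log axis) per library for 9 genes in the 4 groups, with points for libraries, bars for means and lines for 1 SD (n = 3). CHS1 stands at 73.5 in red and 0.525 in yellow at color break, and PG2A at 591 in red at maturity against 4420 to 5610 in the other groups.

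At maturity the same question was asked of fruit of equal age, 55 days after anthesis. No measure of ripeness was used here, so a lasting difference between the tomatoes cannot be told apart from a different progress of ripening. Of 14 flavonoid genes 9 were higher in the red tomato, while PG2A and ACO1, single genes of wall softening and ethylene synthesis, were lower. CHS2 was 15.3-fold higher in red (3.94 ± 0.13, adjusted p = 1.27e-11), CHS1 15-fold (3.90 ± 0.12, adjusted p = 7.67e-12), F3H 12-fold (3.58 ± 0.10, adjusted p = 4.1e-12) and MYB12 8.9-fold (3.15 ± 0.20, adjusted p = 1.24e-08). PG2A, the main polygalacturonase of ripe fruit, which degrades pectin, was 10.4-fold lower in red: 591 ± 34.6 FPKM (n = 3) against 5610 ± 57 in yellow (-3.38 ± 0.05, adjusted p = 5.39e-15). ACO1, an ACC oxidase, was 3.1-fold lower (271 ± 7.37 against 763 ± 8.69 FPKM, adjusted p = 1.66e-13).

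Of the 14 flavonoid genes 9 rose, 2 fell and 3 were not called, also adjusted over the list alone (median 1.66, list test adjusted p = 1.33e-13, adjusted p = 0.0301 with an estimated correlation). Among 9 wall softening genes 0 rose and 3 fell (adjusted p = 6.91e-07, adjusted p = 0.0383 with an estimated correlation): PG2A, MAN4 (-4.07 ± 0.21) and the endoglucanase gene CEL1 (-2.76 ± 0.14). Their list had a median of -0.10, which turned to 0.08 on FPKM rescaled to a fixed total, and a mean of -1.20, and pectate lyase PL was level (0.01 ± 0.04, adjusted p = 0.804). In the ethylene list 3 of 23 fell and 0 rose (adjusted p = 0.00753, adjusted p = 0.149 with an estimated correlation), namely ACO1, ACO6 and E4, an ethylene-responsive gene at 1020 ± 150 FPKM in red and 2430 ± 92.3 in yellow. Of 9 aroma genes 2 fell (adjusted p = 0.0111, adjusted p = 0.149 with an estimated correlation), the lipoxygenases LOXA (-1.52 ± 0.06) and LOXC (-1.26 ± 0.03). Lycopene synthesis had 1 fall in 14, GGPPS2 (-1.53 ± 0.06, list test adjusted p = 0.00753, adjusted p = 0.149 with an estimated correlation). PSY1 was at 2780 ± 43.1 FPKM in red and 1610 ± 9.87 in yellow (0.65 ± 0.02, adjusted p = 2.07e-11), not called, as were CRTISO (-0.05 ± 0.04), CYCB (-0.03 ± 0.06), RIN (0.06 ± 0.04), NOR (-0.01 ± 0.04) and ACS2 (-0.23 ± 0.04). Later carotenoid steps had 1 fall, the violaxanthin de-epoxidase gene VDE (-1.94 ± 0.08), and 1 rise of 10, the zeaxanthin epoxidase gene ZEP (9.49 ± 0.291 FPKM in red, 4.31 ± 0.371 in yellow, adjusted p = 2.56e-07), whose call was lost without replicate 1 of yellow at maturity (0.94) or replicate 3 of red at maturity (0.99).

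Of 15 photosynthesis genes, 8 of which were higher in red at color break, 8 were lower and 1 was higher in red at maturity. Adjusted over the list alone the counts were 9 and 1 (median -1.44, list test adjusted p = 0.0014, adjusted p = 0.149 with an estimated correlation). With limma on log2(FPKM + 1) the median was -0.67 and 4 members were called, and the median was -0.69 on FPKM rescaled to a fixed total and -0.68 after quantile normalization. The photosystem I antenna gene Solyc10g006230 was 5.09-fold lower and the photosystem II gene Solyc09g064500 (Psb28) 7.87-fold lower. The member that rose was psbZ (2.28 ± 0.47), a gene of the plastid genome in plants that the table places on chromosome 1. Markers of seed moved with them: 4 of 5 fell (median -3.76, adjusted p = 0.00753, adjusted p = 0.306 with an estimated correlation), and 5 of 5 fell without replicate 1 of red at maturity (median -6.38, or -5.01 with the 2 genes then at 0 placed at a floor of 3 counts over the group). The oleosin gene Solyc06g060840, a coat protein of seed oil bodies, was at 1.21 ± 0.476 FPKM in red and 15.3 ± 0.677 in yellow. Of 50 cell cycle genes 12 fell, among them histone H2A Solyc01g099410 (-2.03 ± 0.10), and 1 rose, Cyclin-D1-1 (adjusted p = 0.0275, adjusted p = 0.425 with an estimated correlation). Of 70 ribosomal protein genes 6 fell and 1 rose (adjusted p = 6.91e-07, adjusted p = 0.306 with an estimated correlation), and 2 of 12 heat shock genes fell (adjusted p = 0.0181, adjusted p = 0.149 with an estimated correlation). Sugar genes had 4 falls in 20 and a median of 0.03 beside a mean of -0.21 (adjusted p = 0.692), with the invertase inhibitor gene INVINH1 at -1.60 ± 0.09. Defence had 3 rises and 2 falls in 12, with CHI9 at 20.5 ± 0.178 FPKM in red and 5.74 ± 0.399 in yellow. Its falls were lost without 1 library, CHI3 without replicate 3 of red at maturity (-0.94) and Solyc05g054120 without replicate 1 of yellow at maturity (-1.12). Vitamins E and C had 1 of each in 11, GME2 up (1.32 ± 0.06) and VTE4 down (-1.53 ± 0.08), and glycoalkaloids 1 fall in 4, GAME11. No edgeR call fell among 5 chlorophyll genes (4 at an unadjusted p under 0.05), 13 ripening regulators (7), 10 acid genes (8) and 4 cuticle genes (4). Photosynthesis was the only list whose counts differed when adjusted over the list alone.

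Under the naming rule, the largest rise at maturity was in ENSRNA050030024 (chromosome 11), described as eukaryotic large subunit ribosomal RNA, which was 176-fold higher in red (15.4 ± 0.926 against 0.0698 ± 0.0184 FPKM, adjusted p = 2.38e-12), and a group II catalytic intron (ENSRNA050030006, chromosome 11), a kind of intron found in organelle genes, was 63.5-fold higher at 140 ± 7.48 FPKM. As mRNA was captured on oligo(dT), what the reads at these entries measure is not settled. Ribosomal RNA entries together took 0.043% to 0.062% of counts in red at maturity and 0.084% to 0.113% in yellow, the opposite direction. The plastid ribosomal protein gene rpl33 was 3.90 ± 0.55 higher, or 5.83 without replicate 1 of yellow at maturity. The xyloglucan-modifying gene Solyc12g098610 fell 26.6-fold (10.8 ± 1.16 to 0.437 ± 0.0512 FPKM from yellow to red), and the metallothionein-like Solyc06g076140 was 21-fold lower in red, where its libraries held 46.71, 23.03 and 17.24 FPKM. A tonoplast intrinsic protein gene (Solyc03g019820, -4.80 ± 0.47), a poly(ADP-ribose) polymerase gene (Solyc11g067250, -4.56 ± 0.58) and a cysteine protease gene (Solyc11g008260, -4.31 ± 0.59) were detected in red only in replicate 1. Without that library the group is at 0 counts, at least 492-fold, 1320-fold and 1140-fold lower than yellow. Without replicate 2 they were -4.20, -3.96 and -3.72, and without replicate 3 -4.20, -3.96 and -3.71.

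At maturity edgeR called 1781 genes, 521 higher and 1260 lower in red (29.3% higher), and 1923 without replicate 1 of red at maturity. On FPKM rescaled to a fixed total the split was 508 higher and 691 lower (42.4% higher).

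**Figure D3:**
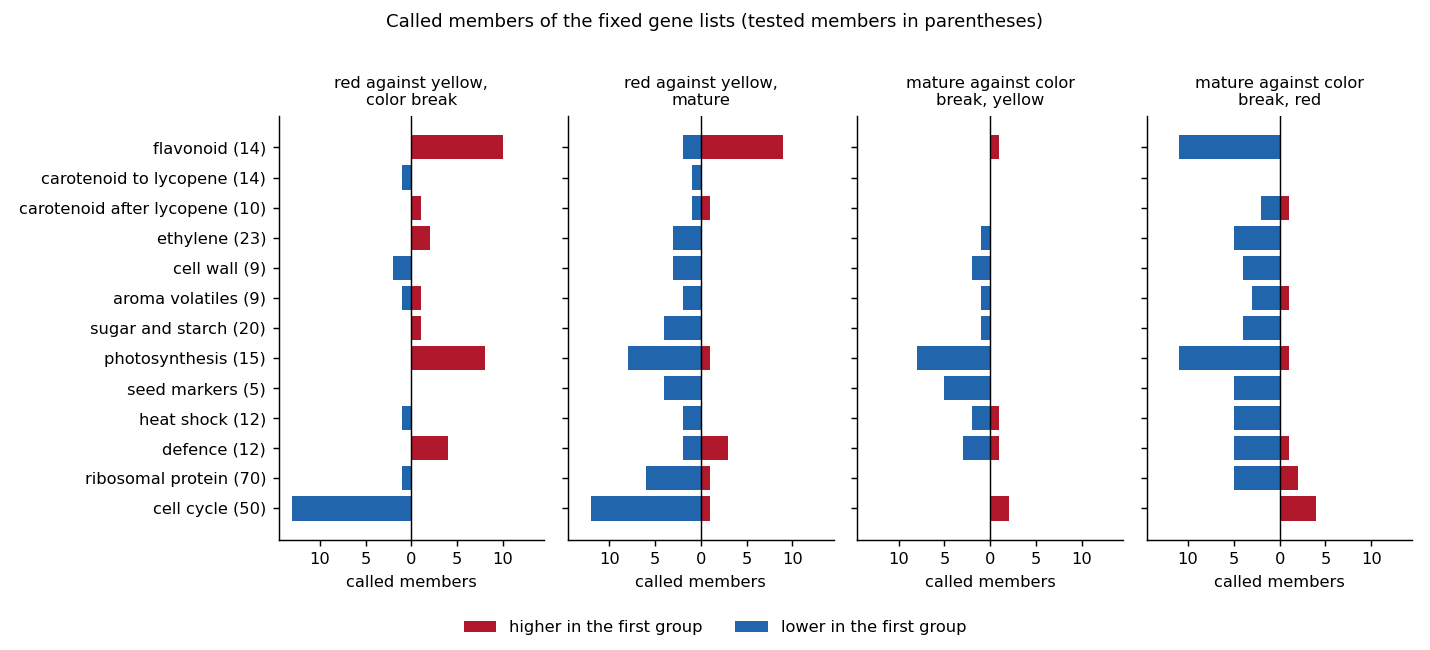
Called genes of 13 lists (tested members in parentheses) in the comparisons of 2 groups, with bars to the right for genes that were higher and to the left for genes that were lower. Flavonoid genes were higher in red at both stages (10 and 9 of 14) and 11 of 14 fell from color break to maturity in red.

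The stage comparison in the yellow tomato asked what changed between color break and maturity. Under the naming rule, 3 of the 5 largest falls were in lipid-transfer protein genes, and none of 13 ripening regulators was called by edgeR. Of these regulators 11 had an unadjusted p under 0.05. The same number passed an adjusted p under 0.05, but none reached the minimum change (largest absolute log2 fold change 0.76). LE16, a non-specific lipid-transfer protein gene, fell 34.2-fold, from 121 ± 9.82 to 3.61 ± 0.836 FPKM (n = 3, -5.10 ± 0.16, adjusted p = 6.95e-11). Its neighbor in the numbering, Solyc10g075100, fell 23.1-fold, another lipid-transfer protein gene, Solyc01g090360, fell from 617 ± 42.6 to 40.4 ± 4.23 FPKM, and the aquaporin gene Solyc06g060760 (TIP23) fell 15.4-fold. A glucan endo-1,3-beta-glucosidase gene (Solyc01g059965), of a family that degrades callose and fungal walls, rose 46-fold, from 0.12 ± 0.0825 to 5.91 ± 0.368 FPKM (5.52 ± 0.26, adjusted p = 2.24e-09), or 6.19 on the log2 scale without replicate 3 of yellow at color break.

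The next largest rises under the naming rule were a LysM domain gene (Solyc01g112080, 3.22 ± 0.12), of a family that binds chitin-type sugars, a pectin acetylesterase gene (Solyc01g102350, 2.54 ± 0.10), a flavin-containing monooxygenase gene (Solyc01g112100, 2.33 ± 0.12) and the chitinase gene CHI9 (2.16 ± 0.17). Of 15 photosynthesis genes 8 fell and 0 rose (adjusted p = 5.52e-05, adjusted p = 0.185 with an estimated correlation), or 4 called with limma on log2(FPKM + 1), with Solyc10g006230 8.64-fold lower and RBCS-2A 4.83-fold lower. All 5 seed markers fell (median -2.50, adjusted p = 0.000901, adjusted p = 0.428 with an estimated correlation), such as the oleosins Solyc02g086490 (29.3 ± 2.36 to 0.903 ± 0.355 FPKM) and Solyc12g010920 (189 ± 11 to 37.2 ± 0.409 FPKM). DESeq2 called 2 of the 5, as it gave no adjusted p for those 2 oleosins and a wider error for Solyc06g034040 (-2.57 ± 1.62, adjusted p = 0.205, against -2.57 ± 0.37 with edgeR). Among 9 wall genes 2 fell, MAN4 (-2.51 ± 0.14) and CEL1 (-1.54 ± 0.11), and 0 rose (adjusted p = 5.42e-05, adjusted p = 0.125 with an estimated correlation), while PG2A was at 5610 ± 57 against 4460 ± 120 FPKM (0.31 ± 0.04, adjusted p = 4.81e-05) and not called.

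Neither carotenoid list had an edgeR call (14 genes with 11 at an unadjusted p under 0.05, and 10 with 7), with PSY1 at 0.18 ± 0.02, CRTISO at 0.43 ± 0.04 and CYCB at 0.22 ± 0.06. CHS1 was the only flavonoid call of 14, from 0.525 to 1.09 FPKM (1.02 ± 0.18, adjusted p = 0.000516), and this call was lost without replicate 2 of yellow at color break (0.92) or at maturity (0.89). ACO6 was the only one of 23 ethylene genes called (-2.03 ± 0.11), with ACO1 at 0.09 ± 0.03 and ACS2 at 0.04 ± 0.04. VI, the vacuolar invertase that splits sucrose, fell from 2330 ± 69.8 to 838 ± 9.31 FPKM (-1.50 ± 0.04, adjusted p = 7.79e-12), the only call of 20 sugar genes. Of 9 aroma genes LOXD fell, a call lost without replicate 3 of yellow at color break (-0.89). Glycoalkaloid genes split, GAME11 down (-2.65 ± 0.19) and GAME36 up (1.14 ± 0.04) of 4. Heat shock had 1 rise and 2 falls in 12, defence 1 rise and 3 falls in 12, and the cell cycle 2 rises and 0 falls in 50 (adjusted p = 0.0264, adjusted p = 0.601 with an estimated correlation), 1 of them histone H2A Solyc01g099410 (1.06 ± 0.10). The other, Cyclin-D1-1, was not called without replicate 1 (1.23) or 2 (0.75) of yellow at color break or replicate 1 (1.04) or 2 (1.14) of yellow at maturity. Ribosomal proteins moved up as a list (median 0.18, adjusted p = 0.000269, adjusted p = 0.601 with an estimated correlation) without an edgeR call among 70 (36 at an unadjusted p under 0.05). The acid and amino acid list also moved up (0 calls of 10, 8 at an unadjusted p under 0.05, adjusted p = 0.0214, adjusted p = 0.182 with an estimated correlation). No edgeR call was made among 13 ripening regulators (11), 5 chlorophyll genes (5), 11 genes of vitamins E and C (7) and 4 cuticle genes (4), where the number at an unadjusted p under 0.05 stands in parentheses. RIN was at -0.01 ± 0.04, NOR at -0.27 ± 0.04, PL at 0.11 ± 0.04 and LOXC at -0.53 ± 0.03. Each list had the same counts adjusted over the list alone. In the yellow tomato edgeR called 1015 genes, 235 higher and 780 lower at maturity.

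**Figure D4:**
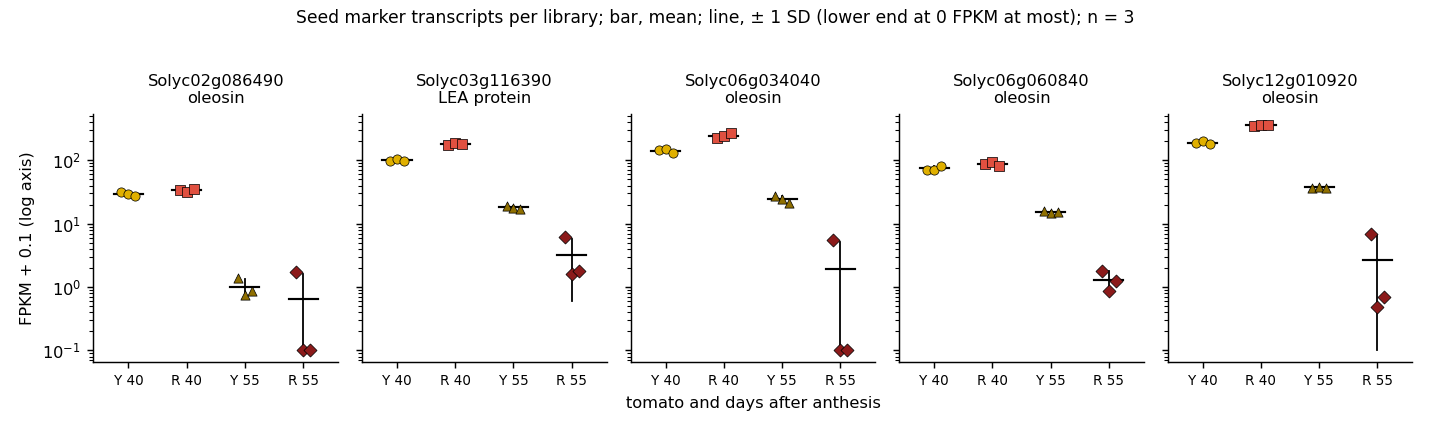
FPKM plus 0.1 (log axis) of the 5 seed markers, 4 oleosin genes and 1 late embryogenesis abundant gene, per library in the 4 groups. All 5 lie lower at maturity in both tomatoes, and in red at maturity replicate 1 lies above replicates 2 and 3.

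The same stage comparison in the red tomato asked what changed on the way to ripe red fruit. Here 11 of 14 flavonoid genes and 11 of 15 photosynthesis genes fell, and so did PG2A and ACO1. CHS1 fell 4.52-fold, from 73.5 ± 2.2 to 18.1 ± 2.31 FPKM (n = 3, -2.18 ± 0.09, adjusted p = 9.62e-11). PG2A fell 8.34-fold, from 4420 ± 163 to 591 ± 34.6 FPKM (-3.06 ± 0.04, adjusted p = 8.49e-15), and ACO1 3.45-fold (-1.79 ± 0.03, adjusted p = 2.1e-14). Solyc10g006230, a photosystem I antenna gene, fell 103-fold, from 43.8 ± 1.87 to 0.471 ± 0.195 FPKM (adjusted p = 8.84e-13).

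Of the 14 flavonoid genes 11 fell, 0 rose and 3 were not called (median -1.94, adjusted p = 4.13e-20, adjusted p = 0.0058 with an estimated correlation). Beside CHS1 they included CHS2 (-2.38 ± 0.10), MYB12 (-1.91 ± 0.16), the cinnamate 4-hydroxylase gene C4H (-2.63 ± 0.12) and the phenylalanine ammonia-lyase gene PAL (Solyc10g086180, -2.30 ± 0.05), the last of these at the entry to the pathway. In wall softening 4 of 9 fell and 0 rose (median -0.95, adjusted p = 1.07e-07, adjusted p = 0.0197 with an estimated correlation): PG2A, MAN4 (-5.24 ± 0.20), CEL1 (-3.26 ± 0.14) and the beta-galactosidase gene TBG4, while PL stood at 1860 ± 156 FPKM against 1420 ± 11.2 (0.23 ± 0.04, not called). Of 15 photosynthesis genes 11 fell and 1, psbZ, rose (median -3.72, adjusted p = 1.63e-10, adjusted p = 0.0151 with an estimated correlation), with RBCS-2A 42.6-fold lower. All 5 seed markers fell too (median -6.30, or -9.65 without replicate 1 of red at maturity, with 2 genes at 0 placed at the floor, adjusted p = 0.000277, adjusted p = 0.197 with an estimated correlation). Among them Solyc06g060840 fell 79-fold, from 88.4 ± 5.98 to 1.21 ± 0.476 FPKM. DESeq2 called 3 of the 5 and gave the other 2 no adjusted p.

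In the ethylene list 5 of 23 fell and 0 rose (adjusted p = 0.00161, adjusted p = 0.0942 with an estimated correlation), with a median of -0.18 that turned to 0.06 on FPKM rescaled to a fixed total. They included ACO6 (50.2-fold, from 104 ± 3.47 to 2.31 ± 0.683 FPKM), ACO5 (-2.47 ± 0.08) and E4 (-1.83 ± 0.09). Of 12 heat shock genes 5 fell (adjusted p = 0.00218, adjusted p = 0.0876 with an estimated correlation), with HSP21, a plastid small heat shock protein, at 321 ± 2.88 against 993 ± 20.7 FPKM. Of 20 sugar genes 4 fell (adjusted p = 0.0476, adjusted p = 0.197 with an estimated correlation), including SUS1 (-1.65 ± 0.05) and INVINH1 (-1.77 ± 0.09). The sugar median of -0.11 turned to 0.05 with the authors' depth, 0.05 on log2(FPKM + 1), 0.13 on FPKM rescaled to a fixed total and 0.02 after quantile normalization. Lycopene synthesis had no edgeR call in 14 genes (8 at an unadjusted p under 0.05), with PSY1 at -0.08 ± 0.02, CRTISO at 0.41 ± 0.04 and CYCB at 0.02 ± 0.06. Later steps had NCED2 up (1.23 ± 0.18) and NCED1 (-1.50 ± 0.05) and VDE (-1.98 ± 0.08) down in 10. Aroma volatiles had 1 rise and 3 falls in 9, with a median of 0.19 and a mean of -0.61 (adjusted p = 0.42), LOXA being down (-2.12 ± 0.06) and LOXC at 0.33 ± 0.03 not called. The rise was LOXB (1.04 ± 0.05), whose call was lost without replicate 3 of red at maturity (0.98).

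Other rises of 1 gene in a list were GAD2, a glutamate decarboxylase that makes GABA (1.09 ± 0.07, the only call of 10 acid genes), GGP1, a vitamin C enzyme (1.15 ± 0.04, the only call of 11), and GAME36 (1.23 ± 0.04), while GAME11 fell 46.6-fold (4 glycoalkaloid genes). Defence had 1 rise, CHI9, and 5 falls in 12, the largest in size Solyc05g054120 (-3.76 ± 0.45). Of 70 ribosomal protein genes 2 rose and 5 fell (adjusted p = 0.0123, adjusted p = 0.585 with an estimated correlation). Of 50 cell cycle genes 4 rose and 0 fell (adjusted p = 0.0227, adjusted p = 0.551 with an estimated correlation), led by Cyclin-D1-1 (3.12 ± 0.38). There was no edgeR call in 13 ripening regulators (10 at an unadjusted p under 0.05), 5 chlorophyll genes (3) and 4 cuticle genes (1). RIN was at 0.06 ± 0.04, NOR at -0.19 ± 0.04 and ACS2 at 0.35 ± 0.04. Each list had the same counts adjusted over the list alone.

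The largest rises under the naming rule were again the ribosomal RNA ENSRNA050030024 (115-fold) and the group II intron ENSRNA050030006 (76.1-fold), then rpl33 (3.01 ± 0.51), the gene described as WALLS ARE THIN 1 (Solyc04g080940, 7.77-fold, 1.18 ± 0.298 to 10.3 ± 1.09 FPKM), a vacuolar auxin transporter in other plants, and a sulfotransferase gene (Solyc05g011890, 5.9-fold). Solyc06g075990, described as DSI-1VOC, had 2990 counts in red at color break and 0 at maturity, at least 1060-fold lower. The lipid-transfer gene Solyc01g081600 went from 618 counts to 0, at least 219-fold lower. The tonoplast gene Solyc03g019820 (-8.73 ± 0.41), the succinate dehydrogenase subunit gene Solyc04g055030 (-8.67 ± 0.35) and the hexosyltransferase gene Solyc01g100830 (-7.84 ± 0.47) fell next. Without replicate 1 of red at maturity they were at 0 counts, at least 7490-fold, 687-fold and 1690-fold lower, and without replicates 2 or 3 the first stood at -8.13 and -8.12 and the last at -7.25 and -7.24.

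In the red tomato edgeR called 2471 genes, 628 higher and 1843 lower at maturity (25.4% higher), and 2585 without replicate 1. On FPKM rescaled to a fixed total the split was 765 higher and 1284 lower (37.3% higher).

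The last comparison tested whether the stage change itself differed between the tomatoes, as the red change minus the yellow change. The change was lower in red for 12 of 14 flavonoid genes, and for PG2A and ACO1. The difference was -3.19 ± 0.20 for CHS1 (adjusted p = 2.39e-08), -1.31 ± 0.28 for MYB12 (adjusted p = 0.00162), -3.37 ± 0.06 for PG2A (adjusted p = 1.61e-13) and -1.88 ± 0.04 for ACO1 (adjusted p = 2.03e-12, n = 3 per group). For LOXC it was 0.86 ± 0.04 (adjusted p = 1.3e-09), for PSY1 -0.27 ± 0.03 and for ACS2 0.31 ± 0.06, all under the minimum, and RIN (0.07 ± 0.05), NOR (0.08 ± 0.05), PL (0.12 ± 0.06), CRTISO (-0.02 ± 0.06) and CYCB (-0.20 ± 0.08) were not called.

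Of 14 flavonoid genes 12 had a lower change in red and 0 a higher one (adjusted p = 9.23e-19, adjusted p = 0.00502 with an estimated correlation). Photosynthesis genes had 11 lower of 15, or 12 adjusted over the list alone (median -2.31, adjusted p = 1.31e-07), ethylene 5 of 23 (adjusted p = 9.48e-05), wall softening 3 of 9 (adjusted p = 0.000278), heat shock 3 of 12 (adjusted p = 0.000558) and later carotenoid steps 2 of 10 (adjusted p = 0.0104), with 0 higher in each and for each of these 5 lists adjusted p = 0.0533 with an estimated correlation. The ethylene median of -0.21 turned to 0.08 after quantile normalization. Seed markers had 4 of 5 lower, or 2 with DESeq2 (median -4.00, or -7.28 without replicate 1 of red at maturity and -5.20 with the 2 genes then at 0 at the floor, adjusted p = 0.00204, adjusted p = 0.31 with an estimated correlation), and ribosomal proteins 9 lower and 1 higher of 70 (adjusted p = 1.31e-07, adjusted p = 0.332 with an estimated correlation). Aroma volatiles (1 higher, 3 lower of 9), sugar (1 and 5 of 20), defence (1 and 2 of 12) and the cell cycle (1 and 0 of 50) passed no list test. Glycoalkaloids (0 and 1 of 4) and the cuticle (1 and 0 of 4) were not tested as lists. No edgeR call was made for lycopene synthesis (14 genes, 11 at an unadjusted p under 0.05), chlorophyll (5 genes, 3), ripening regulators (13 genes, 6), acids (10 genes, 7) and vitamins E and C (11 genes, 7). Photosynthesis alone had other counts adjusted over the list alone.

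Under the naming rule the most positive differences were those of ENSRNA050030024 (7.00 ± 0.46), ENSRNA050030006 (5.31 ± 0.51), rpl33 (3.44 ± 0.86, or 5.37 without replicate 1 of yellow at maturity), the lipoxygenase gene Solyc01g099180 (2.52 ± 0.64, or 1.36 without replicate 3 of yellow at color break) and the gene Solyc09g082790 (2.32 ± 0.18), described as a homolog of the meiotic recombinase DMC1. Among the most negative, the stage fall of Solyc06g075990 was at least 211 times as large in red as in yellow, where it fell 5.03-fold, and that of Solyc01g081600 at least 54.7 times as large. FAS protein gene Solyc11g071810 (-6.62 ± 0.51) stood at -7.57 and -6.03 without replicates 2 and 3 of red at maturity. Solyc04g055030 (-5.86 ± 0.49) stood at -5.27 without replicate 3, and Solyc11g067250 (-5.79 ± 0.71) at -5.19 and -5.18 without replicates 2 and 3. Without replicate 1 both were at 0 counts in red at maturity, with stage falls at least 97.3 and 3090 times as large in red as in yellow. The test called 1954 genes, 480 with a higher and 1474 with a lower change in red (24.6% higher), and 2085 without replicate 1 of red at maturity. On FPKM rescaled to a fixed total the split was 599 and 947 (38.7% higher).

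Across the 15974 genes, which are not independent replicates, the difference between the tomatoes at color break and at maturity correlated weakly (Pearson r = 0.11, Spearman rho = 0.134), with no library shared. Without replicate 1 of red at maturity r was 0.037 and rho 0.126. Called at both stages with the same sign were 322 genes, 150 higher and 172 lower in red, CHS1, F3H, MYB12, LOXC and GGPPS2 among them, where independent lists would share 47.7. A further 220 were called with opposite signs (62.8 for independent lists), of which 196, ACO6 among them, were higher in red at color break and lower at maturity. The stage changes of the tomatoes correlated more closely (r = 0.533, rho = 0.434), with 753 genes called in both with the same sign, 103 higher and 650 lower at maturity (99.2 for independent lists), and 70 with opposite signs (57.8).

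PSY1 lies on chromosome 3 at 4350647 to 4356442. The next gene named here, Solyc03g031870, chosen after its values were seen, lies 4161 bases farther at 4360604 to 4363707. It was at 115 ± 5.92 FPKM in yellow and 1.91 ± 0.112 in red at color break (-5.91 ± 0.62, adjusted p = 4.1e-06). At maturity it was at 136 ± 9.65 in yellow and 0.838 ± 1.45 in red (log2 fold change -7.495). In red at maturity replicate 1 held 395 counts and replicates 2 and 3 held 0.

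**Figure D5:**
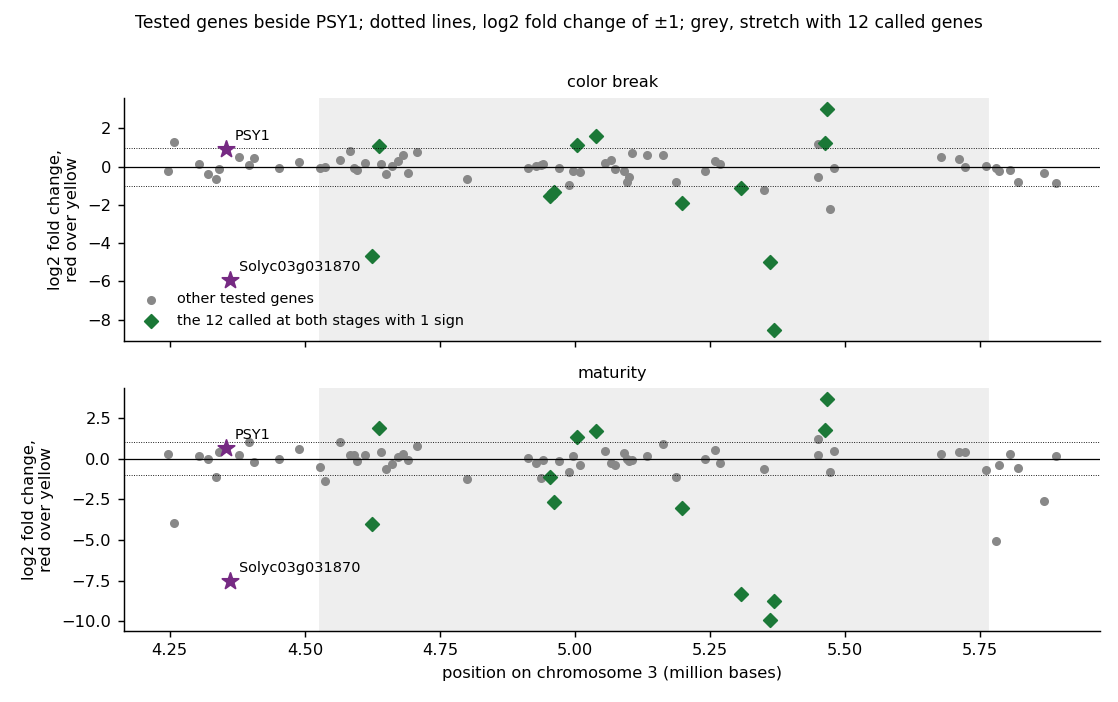
Log2 fold change, red against yellow, of the tested genes by position on chromosome 3 in bases, at both stages. Stars mark PSY1 and Solyc03g031870, diamonds the 12 genes of the grey stretch that differed the same way at both stages, and the stretch runs from 4527816 to 5763802.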

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

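The tests that regrouped the libraries and the test of the red stage falls against seed RNA were set before their results were seen. The tests of replicate 1 of red at maturity, of the falls also called in yellow, of the scaling and of the seed ratio on the log2 scale and without that replicate were chosen after the result was seen.

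The results picked out here are those where the stage change differed between the tomatoes by a test of the difference itself. It differed in 1954 genes, and 60 of the 200 possible splits of the libraries were fitted, the real one included. The highest of the other 59 gave 1465, so the real split was the only 1 with as large a result. Whether a random split could do as well is not settled by this. Splits that mix the tomatoes put their difference into the residual, which holds their counts near 0. The split with all line labels of 1 stage exchanged, which would leave the residual as it is, was not among those fitted. The count also says nothing of chance between plants. The 7 other splits that kept the line labels at maturity gave 1194 to 1465 genes and the 3 that kept them at color break 273 to 415, since their term holds that stage's difference between the lines, and the rest gave at most 1. Splits of 3 against 3 libraries number 10 and are too few for a share under 0.05. The real counts there were 991, 1781, 1015 and 2471 and the highest of the other splits 0, 2, 0 and 1 for red against yellow at color break and at maturity and for the stages in yellow and in red.

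Among single genes, red minus yellow, the difference was 7.00 for the ribosomal RNA ENSRNA050030024, 5.31 for the group II intron ENSRNA050030006, 3.44 for rpl33 (5.37 without replicate 1 of yellow at maturity), 2.52 for the lipoxygenase gene Solyc01g099180 (1.36 without replicate 3 of yellow at color break) and 2.32 for Solyc09g082790. It was -3.19 for CHS1, -1.31 for MYB12, -1.88 for ACO1 and -3.37 for PG2A, and for the flavonoid list the adjusted p was 0.00502 with an estimated correlation. It was -6.62 for Solyc11g071810 (-7.57 and -6.03 without replicates 2 and 3 of red at maturity), -5.86 for Solyc04g055030 (-5.27 without replicate 3) and -5.79 for Solyc11g067250 (-5.19 and -5.18 without replicates 2 and 3). Without replicate 1 the last 2 genes are at 0 counts in red at maturity, with falls at least 97.3 and 3090 times as large as in yellow. The fitted -10.65 of Solyc06g075990 and -8.70 of Solyc01g081600 depend on the prior count, as both had 0 counts in red at maturity, and are no bounds.

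The first pattern concerns 107 genes with at most 5 counts in replicates 2 and 3 of red at maturity and at least 10 counts per 1e6 (CPM) in another group, many of which replicate 1 holds. One mix of 1.05% yellow color break, 1.06% red color break and 0.97% yellow mature RNA, fitted to these same genes, put 84.1% of them within 2-fold. In replicate 1, 40 genes higher in yellow at both stages had a median excess of 2% of their yellow level (95% bootstrap interval of the median 1.32 to 4.12). The excess was positive in 28 of the 40. These genes were picked for low levels in replicates 2 and 3, which can itself raise the excess. Reads or RNA of other groups may be part of the pattern. Against so simple a mix, a fit over all 15974 genes gave 10.41% from other groups, in other shares. These were 0.0% yellow color break, 1.9% red color break and 8.51% yellow mature. Solyc06g075990 had 0 counts where the first mix predicts 16. Seed tissue cannot be told apart for the set, since all 5 seed markers lay above both other replicates, at 1.9% to 4.96% of red color break, and rest on the same library, but the level of Solyc03g031870, 7.46 CPM, argues against seed for that gene, as it lies above its red color break level of 5.7 ± 0.327. The same level argues against a less ripe red fruit for that gene, which was chosen after its values were seen. For the set a less ripe red fruit cannot be told apart. Only 1 of the 107 genes, Solyc03g031870 itself, and 3 of the 40 lay above their red color break level by more than 2 SD.

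The second pattern is that 1843 genes were lower at maturity in red and 780 in yellow. Loss of seed RNA would lower genes in both tomatoes in the ratio of the 5 markers, if seed loss is what lowered those, which was not tested. The markers' drop in mean CPM in yellow was 0.434 to 0.863 of that in red. The median over the 1843 genes was 0.351 (95% bootstrap interval of the median 0.335 to 0.365, genes resampled as if independent). Without replicate 1 of red at maturity it was 0.349 against 0.431 to 0.849 in the markers. By the bound set beforehand the first argues against seed as the whole cause where seed RNA adds to CPM. Only 5 markers set that bound and the genes were picked by their fall in red, so seed is not excluded. Log2 ratios decide nothing, at 0.301 against 0.325 to 0.822, but 0.29 against 0.208 to 0.496 without that library. Every scaling run left at most 37.3% of the called genes in red higher, which argues against scaling as the reason why falls outnumber rises there. The number of falls did move. It was 1621 in red and 755 in yellow with the authors' depth, and 1284 and 555 with limma on FPKM rescaled to a fixed total. For the 650 genes called in both tomatoes (median 0.524, bootstrap interval 0.492 to 0.563) seed cannot be told apart from ripening. Nor can it for the 1193 others (median 0.213, bootstrap interval 0.192 to 0.231). There the bound set beforehand decides nothing, because the genes were picked by the yellow change itself. Of the 1843 genes 498 lie within the range of the markers and 308 were not lower in yellow, and a stronger ripening program in red by 55 days stays open.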

How the results depend on the processing

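Library totals without TMM and the depth implied by the authors' FPKM were chosen after the data were seen, and the other tests of this part before. The counts are given in the order red against yellow at color break and at maturity, stages in yellow, stages in red, and difference of stage changes (991, 1781, 1015, 2471 and 1954 genes).

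DESeq2 gave 936, 1730, 935, 2408 and 1928 genes and left 67 genes without an adjusted p. Median-ratio scaling gave 997, 1782, 1014, 2476 and 1960, totals without TMM 991, 1730, 1007, 2463 and 1917, and the authors' depth 993, 1738, 1007, 2479 and 1922. Leaving out 1 library at a time gave 952 to 1007, 1718 to 1923, 999 to 1037, 2416 to 2585 and 1885 to 2085 genes, a correlation of the line differences of 0.037 to 0.128, the lowest without replicate 1 of red at maturity, and of the stage changes of 0.499 to 0.536. With the replicate number as a block, 983, 1786, 1013, 2473 and 1951 genes were called. To look for pairing, the deviations of each library from its group mean were correlated across genes between groups. The same replicate number went with a higher r of these deviations between the stages in yellow (0.067 to 0.085, different numbers -0.06 to -0.011). It went with a lower r between the tomatoes at color break (-0.053 to -0.041 against -0.036 to 0.085) and with neither elsewhere, so pairing by the block is not shown.

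Counts moved by over 1.5 times under these choices. A mean FPKM of at least 5 gave 345, 758, 354, 983 and 824 among 10617 tested genes of the 15974, and kept 341 of the 991 calls at color break. The calls fell by more than the tested genes, so they lay more often in genes under that mean. An adjusted p alone gave 6632, 9124, 6321, 10271 and 7457, because no minimum change was asked. Without a filter the stages in red gave 3822. With limma on log2(FPKM + 1) the counts were 519, 942, 563 and 1205, without trend 518, 940, 559 and 1204, and with array weights 529, 987, 568 and 1249, while the stages in red moved less (1654, 1651 and 1693). The counts were, after quantile normalization, 548, 889, 559, 1583 and 1192, and with a pseudocount of 5, 184, 356, 220, 741 and 519, while one of 0.1 gave 903, 1629, 939, 2406 and 1877, within 1.5 times. A pseudocount shrinks changes of genes with low values by construction. No other cause was tested.

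Of 85 list tests 36 passed, 7 with an estimated correlation, 74 with fry, 25 on log2(FPKM + 0.1) and 36 with a replicate block. By list, limma on log2(FPKM + 1) called 5 ribosomal protein genes against 10 with edgeR in the difference of stage changes, and 2 defence genes against 5 at maturity and 4 in yellow. For named genes, 6461 alternatives over 234 results gave 6219 the same, 217 weaker, 25 stronger and 0 reversed, with 78 sign changes where neither fit made a call. Of the 217, 65 came from the pseudocount of 5, 26 from quantile normalization, 25 from limma on log2(FPKM + 1), 15 from FPKM rescaled to a fixed total and 2 from DESeq2. Among the named genes' calls that ended without 1 library are those of ZEP, LOXB, LOXD, CHS1 in yellow and Solyc01g099180, given in the report with the library. For lists, 340 alternatives gave 262 the same, 40 weaker, 38 stronger and 0 reversed.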

Other observations

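All tests of this part were chosen after the result was seen, the GO terms and the window on chromosome 3 among them, and the 50-gene window was the only size tried.

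GO terms overlap the fixed lists and add the following groups. Among genes higher in red at color break, chitin binding held 6 of 11 tested genes (expected 0.5, adjusted p = 0.00017), and among genes higher at maturity in yellow 7 of 11 (0.2, adjusted p = 1.2e-08), with CHI9, a chitinase, at 1.26 ± 0.28, 4.66 ± 1.01, 5.74 ± 0.399 and 20.5 ± 0.178 FPKM in yellow and red at color break and yellow and red at maturity. Nutrient reservoir activity, the term of seed storage proteins, fell with the stage in both tomatoes (9 of 11 genes in yellow, adjusted p = 2e-08, and 10 of 11 in red, adjusted p = 8.58e-07), as did lipid storage in yellow (8 of 13, adjusted p = 4.46e-06). The nucleosome held 13 of 55 genes lower in red at color break (expected 1.0, adjusted p = 9.4e-09). Plastid terms went both ways at maturity. All 11 genes of the photosynthetic light reaction (expected 0.3, adjusted p = 2.44e-14), 22 of 137 of the plastid (adjusted p = 1.63e-08) and 12 of 113 of the chloroplast thylakoid membrane (adjusted p = 0.00411) were higher in red, while 37 of the same 113 (adjusted p = 2.06e-11) and 19 of 30 of photosystem II (adjusted p = 2.2e-11) were lower. The named genes psbZ and rpl33, which rose, are plastid genes in plants and lie in the table on chromosomes 1 and 9, so copies of plastid sequence in the nuclear chromosomes and the plastid itself cannot be separated here.

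The third pattern lies beside PSY1. Of the 322 genes that differed the same way at both stages, 12 fell in a window of 50 tested genes on chromosome 3, in a stretch of 56 genes from 4527816 to 5763802 that starts 171374 bases after PSY1. In 10000 permutations the fullest window held 5 genes at the median and 9 at most, which argues against an even spread (p = 0.0001, the smallest they can give). Solyc03g033825 (5457621 to 5466076) and Solyc03g033830 (5464910 to 5466742), both higher in red, overlap and could share reads, which the permutations leave out. By whole chromosome, such genes were 40 of 1712 tested genes on chromosome 3 (2.3%). The highest share was on chromosome 9 (51 of 1158, 4.4%). Of the 12, 58.3% were lower in red and the others higher, which argues against reads lost from one line as the cause of all 12. The largest differences at color break were lower in red: Solyc03g033745 (-8.523), Solyc03g033740 (-4.968) and Solyc03g032080 (-4.646). The largest rise was 3.007 (Solyc03g033830). For the genes lower in red, loss of reads cannot be told apart. A region of different ancestry in the tomatoes may lie there, which no test here reached. Between PSY1 and that stretch, Solyc03g031870 held 8.24 ± 0.499% and 8.42 ± 0.652% of the PSY1 level in yellow at color break and maturity. Its stage change there, 0.22 ± 0.47, differed from that of PSY1 by 0.03 ± 0.47. In yellow, reads running on from PSY1 cannot be told apart from a gene of its own. PSY1 changed by only 0.18 ± 0.02 there, and a steady gene would keep the same ratio. In red at color break PSY1 stood at 2554.71 to 2697.83 FPKM and Solyc03g031870 at 1.91 ± 0.112. That argues against such reads in both tomatoes alike.

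In 49 genes, 46 of them tested, a library had 0 counts where both other replicates of its group had at least 100, in 74 cases over the 4 groups. Replicate 1 of red at maturity had at least 100 counts in 24 genes that were at 0 in replicates 2 and 3, against 1 to 7 such genes in each other library.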
